A study of Ziziphus jujuba var. spinosa with 24 samples.

How the data were processed

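Sequenced total RNA of sour jujube leaves was analysed from 24 libraries, 3 in each of 8 groups made up of 2 ploidies and 4 treatments, as the sample labels give them. The labels number the libraries of a group 1 to 3 but do not say that they came from separate plants, so p-values measure the spread between these libraries, which may be technical. Equal amounts of total RNA entered each library, so levels are shares of the RNA and not amounts per cell, and a general rise or fall of all transcripts with ploidy would not be seen. The submitters' processing notes name HISAT2 and StringTie without versions; the genome build, the annotation and the use of strand were not given in the sources used here.

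The values tested were gene counts, deposited as whole numbers per gene and library and not normalized, per the file headers. The deposited tables also held FPKM values (fragments scaled by transcript length and library total), 1 table per group, per the file headers. The unit was checked against the counts: transcript lengths derived from the ratio of both agreed between libraries, with quartiles of the relative length between 0.99 and 1.003. These tables list genes that reach 0.1 in at least 1 library of the group. FPKM values served only an alternative test. Every column of both kinds of table matched 1 library by name.

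The count table listed 32527 genes, of which 3073 had no count in any library. Of the 29293 identifiers of the LOC form, 19767 were found in a reference table of the ASM3175591v1 assembly, which was used for gene names, gene classes and the order of neighbouring genes, and 3234 further identifiers were gene models without a name. The table pairs 20 genes with established names. Of these, LFY with 104 and AP1 with 2 counts over all libraries did not reach the filter, and the other 18 were tested and counted in every comparison, whatever their values. Genes that share reads with a near-identical copy or overlap a neighbour are uncertain, since the sources do not say how such reads were counted.

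Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr by group, which left 25829, libraries were scaled by the trimmed mean of M values (TMM), and a single model with 1 mean per group over all 24 libraries was fitted with robust dispersions, leaving 16 residual degrees of freedom. Each comparison was a contrast of group means, tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested and called at an adjusted p under 0.05. The 6 drought contrasts, 4 ploidy contrasts and 3 interactions were fixed before the data were examined, and so were the gene naming rule and most alternatives. A contrast of the ploidies averaged over the treatments, and a mean response size per library, were added after the results were seen. Levels are given as CPM, counts scaled to the library total with the TMM factors. Standard errors of the log2 fold change were derived by dividing its absolute value by the square root of the test's F statistic. They therefore hold no information beyond the fold change and its p-value. Responses of both ploidies were compared by the overlap of calls, beside the product of the list lengths divided by the genes tested, and by Pearson's r.

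The naming rule took, in each contrast, genes with the largest fold change among those called, with a mean of at least 5 CPM over the libraries and all 3 libraries of one group beyond all 3 of the other, limited here to at most 2 per direction. It also required an informative description and named members of gene lists chosen by description, such as abscisic acid metabolism, dehydrins, photosystems or heat shock proteins. No source used here pairs the identifiers with descriptions, so that condition was dropped and the lists and their tests were not evaluated. Of the 32 picks of the rule so relaxed, 16 were genes that stood near 0 in one library and high in another of the same group (the highest at 5 CPM or more and at least 50 times the lowest). Such genes were left out of the picks after the data were seen, and they stayed in all counts.

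On counts simulated from the real means and library sizes, with 200 genes changed among 25829, the edgeR model recovered 36% of 2-fold and 85% of 4-fold changes for the control ploidy comparison, with 3 false calls among 124. For diploid drought at 12 h it recovered 41% and 74%, and for the ploidies at 48 h 40% and 80%. The changed genes were drawn from those with at least 1 CPM, and all others were set equal between the groups compared. The real diploid comparison at 12 h called 7794 genes beside 118 in the simulation, so the 41% and 74% do not describe recovery there. DESeq2, in the simulated control ploidy comparison, recovered 47% and 91% but made 73 false calls among 211, and limma 40% and 83% with 19 among 142. In the simulation limma ran on log2 counts scaled to the library total, without transcript lengths. Its figures therefore do not describe limma on FPKM, the alternative used on the real data.

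The alternatives were DESeq2 1.42.0 with its Wald test, limma 3.58.1 on log2(FPKM + 1), relative log expression, upper quartile or library-total scaling, no filter or a mean of at least 1 CPM, only the libraries compared in the model, the replicate number as a block, an adjusted p under 0.01 or a change of at least 2-fold, each library left out in turn, and other splits of the libraries. Libraries of a group were compared for duplicates and none were found. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.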

Results

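The series measured gene transcripts by RNA sequencing in leaves of sour jujube, a wild relative of the cultivated jujube tree, in diploid plants and in autotetraploid plants, which carry a doubled set of the same chromosomes. Plantlets came from tissue culture and were put under drought with polyethylene glycol, an osmotic agent that holds water back from the plant, at concentrations raised in daily steps. Leaves were taken from untreated controls and after 6, 12 and 48 h, so that the 24 libraries formed 8 groups of 3, a control and 3 drought times in each ploidy. The title of the series asks why the autotetraploid tolerates drought better. Library totals ran from 30750412 to 50404402 counts, with a median of 37199250, and 25829 genes had enough counts to be tested. Of these, 18 carried an established gene name, among them both rubisco activase genes, 3 expansin genes, an aquaporin, a catalase and 5 genes often used as expression references. The labels give 20% polyethylene glycol as the final concentration for every drought library. How 6, 12 and 48 h relate to the daily steps was not stated, so the concentration at each harvest is uncertain. The hour of day of each harvest was not given in the sources used here either. Differences between the control and the 6 and 12 h leaves, described below as drought responses, therefore also hold any difference with the hour of day.

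The first principal component of the log2 expression values, with 18.5% of the variance, placed all 12 libraries taken at 6 and 12 h on one side and all 12 control and 48 h libraries on the other. The second, with 9.29% of the variance, ran from the diploid controls at 40.5 to 69.2 to the autotetraploid 48 h libraries at −93.7 to −79.2. Replicate 3 of the autotetraploid at 12 h lay at −56.8 on this component, apart from the other libraries of its group.

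**Figure D1:**
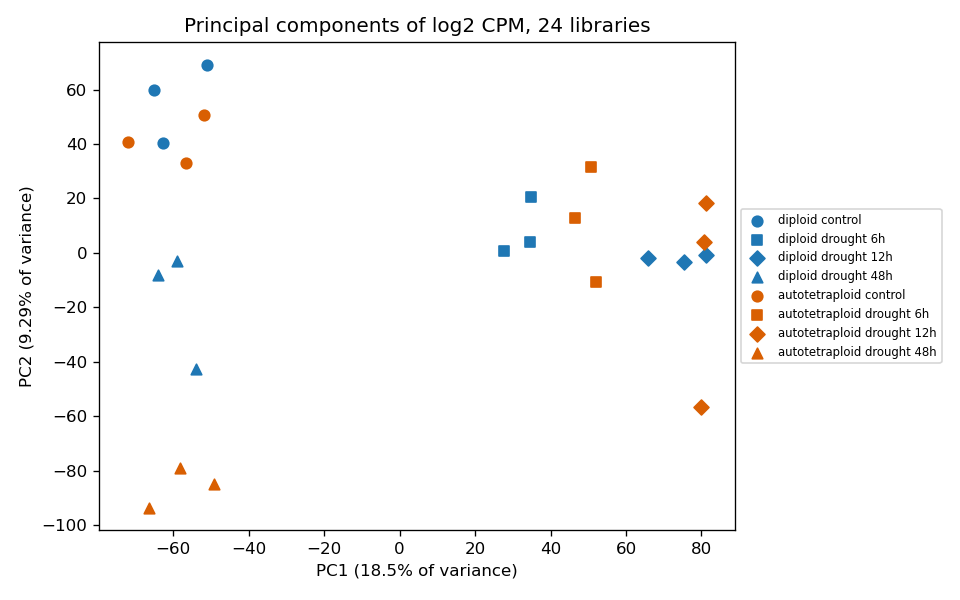
Principal components 1 (18.5% of the variance, horizontal axis) and 2 (9.29%, vertical axis) of log2 CPM (counts scaled to the library total) over 24 libraries, 1 point per library, with colour for ploidy and marker shape for treatment. The 6 and 12 h libraries lie at positive values of component 1 and the control and 48 h libraries at negative values.

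The first comparison asked how leaves of the diploid responded after 6 h of drought. Transcripts of the expansin EXPA5, a protein that loosens cell walls, fell from 397 ± 80.6 CPM in the controls (SD, n = 3) to 130 ± 37.6 CPM, a log2 fold change of −1.62 ± 0.35 (SE, adjusted p = 0.0027). GAPDH, the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, fell from 2180 ± 187 to 1470 ± 33.3 CPM (SD, n = 3; adjusted p = 2.1e-05), and the alpha-tubulin gene TUA from 1010 ± 107 to 693 ± 82.9 CPM (SD, n = 3; adjusted p = 0.0089). Both genes are widely used as constant references, and they fell by 0.57 and 0.54 on the log2 scale. The reference genes ACT1, EF1-gamma and EF1-alpha did not pass, with log2 fold changes of 0.37, 0.02 and −0.27 (adjusted p = 0.18, 0.86 and 0.062). Of the 18 named genes, 7 were lower, none was higher and 11 did not pass the test. Adjusted over the list alone, which was not fixed before the data were seen, 8, 11 and 5 passed in the diploid at 6, 12 and 48 h, and 8, 10 and 6 in the autotetraploid. Over all genes tested, 5510 passed an adjusted p of 0.05, 2944 of them higher and 2566 lower, and 986 and 834 of these differed at least 2-fold. The steepest rises included LOC107429253, from 3.15 ± 0.935 to 175 ± 26 CPM (SD, n = 3; adjusted p = 7.8e-12), and LOC107414343, from 7.74 ± 3.94 to 810 ± 42.3 CPM (SD, n = 3; adjusted p = 3.8e-07). LOC107412003 fell from 235 ± 18.2 to 4.15 ± 0.0249 CPM (SD, n = 3; adjusted p = 4.2e-13). Names other than these identifiers were not paired with the genes in the sources used here. For each of these picked genes all 3 libraries of one group lay beyond all 3 of the other. The rubisco activase RCA1 was lower by a log2 fold change of −0.66 ± 0.20 (SE, adjusted p = 0.026), a call that ended without diploid control replicate 1 (−0.50) or without diploid 6 h replicate 1 (−0.45). With only the 6 libraries compared in the model, 3570 genes passed, and RCA1 did not. The other rubisco activase, RCA2, had a higher mean at 6 h, 13900 ± 3580 against 10100 ± 2540 CPM (SD, n = 3). Its log2 fold change of 0.46 ± 0.20 (SE, adjusted p = 0.12) did not pass.

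At 12 h the transcripts of rubisco activase, the chaperone that clears inhibitors from the active site of the carbon-fixing enzyme rubisco, were far lower in the diploid. RCA1 fell from 3110 ± 618 to 202 ± 26.3 CPM (SD, n = 3), a log2 fold change of −3.94 ± 0.23 (SE, adjusted p = 2.3e-10), and RCA2 from 10100 ± 2540 to 3310 ± 576 CPM (SD, n = 3), a change of −1.61 ± 0.21 (SE, adjusted p = 7.5e-06). Catalase, which breaks down hydrogen peroxide, fell from 2640 ± 404 to 1470 ± 180 CPM (SD, n = 3; adjusted p = 5.8e-05). GAPDH fell to 1100 ± 29.8 CPM (SD, n = 3; adjusted p = 9.6e-09). The elongation factor gene EF1-gamma was the single named gene that was higher, by a log2 fold change of 0.23 ± 0.06 (SE, adjusted p = 0.0094), which did not pass with only the 6 libraries compared in the model, beside 10 that were lower and 7 that did not pass. The aquaporin ZjPIP2, of a family of water channels, fell from 208 ± 27.3 to 42.8 ± 9.66 CPM (SD, n = 3), a log2 fold change of −2.28 ± 0.74 (SE, adjusted p = 0.026). That call ended without diploid control replicate 1 (−2.17) and without diploid 12 h replicate 1 (−2.47), 2 (−2.21) or 3 (−2.16). In all, 7794 genes passed, 3780 higher and 4014 lower, and 1210 and 1804 of them differed at least 2-fold. LOC107411546 rose from 0.255 ± 0.145 to 34.6 ± 2.02 CPM (SD, n = 3; adjusted p = 4.4e-07), and LOC107429528 fell from 119 ± 13 to 0.911 ± 0.0975 CPM (SD, n = 3; adjusted p = 5.1e-13). Scaling by library totals alone moved the median gene by 0.128 on the log2 scale and turned the split to 5333 higher and 2981 lower, which is 64.1% higher beside 48.5%. No named gene called in any drought comparison changed sign under the 3 other scalings, and 37 of the 40 such calls held under all 3.

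At 48 h far fewer genes passed in the diploid than at 6 and 12 h. RCA1 stood at 4120 ± 419 CPM, catalase at 3530 ± 102 CPM and GAPDH at 2190 ± 210 CPM (SD, n = 3), and none of these differed from the control at the threshold, with adjusted p-values of 0.29, 0.092 and 0.98 and log2 fold changes of 0.40, 0.42 and 0.01. TUA was the only one of the 18 named genes to pass, at 676 ± 104 CPM against 1010 ± 107 CPM (SD, n = 3; adjusted p = 0.04), and 17 did not; adjusted over the list alone, catalase, EXPL1, EXPA5 and EF1-gamma passed too. LOC107429528, far from the control at 12 h, stood at 158 ± 27.2 CPM and LOC107411546 at 0.292 ± 0.0123 CPM (SD, n = 3). EXPA5 had a mean of 192 ± 33.2 CPM against 397 ± 80.6 in the control and ZjPIP2 one of 658 ± 119 against 208 ± 27.3 CPM (SD, n = 3), neither past the threshold over all genes, with adjusted p-values of 0.11 and 0.23. LOC107421878 rose from 1.07 ± 0.562 to 27.1 ± 15.4 CPM (SD, n = 3; adjusted p = 0.013), a call that ended without diploid control replicate 2 (4.94 on the log2 scale, against 4.66). In all, 520 genes passed, 285 higher and 235 lower. This count rested on single libraries: it was 849, 36 and 173 without diploid control replicates 1, 2 and 3, and 231, 136 and 88 without diploid 48 h replicates 1, 2 and 3. It was 25 with only the 6 libraries compared in the model, TUA and LOC107421878 not among them, and 1827 by DESeq2, and the call of TUA ended in 5 of 6 fits that left out a library, with log2 fold changes of −0.65 to −0.45. The TUA call also ended with the replicate number as a block.

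In the autotetraploid at 6 h, 6 of the 7 named genes that were lower in the diploid were lower too. EXPA5 fell from 373 ± 141 to 82.1 ± 15.2 CPM (SD, n = 3), a log2 fold change of −2.18 ± 0.36 (SE, adjusted p = 0.00018), and EXPA4 from 417 ± 69.6 to 183 ± 47.8 CPM (SD, n = 3; adjusted p = 0.0037). RCA1 fell from 2710 ± 301 to 1310 ± 251 CPM (SD, n = 3; adjusted p = 9e-04), GAPDH from 2230 ± 49.2 to 1520 ± 82.6 CPM (SD, n = 3; adjusted p = 2.1e-05), and TUA from 1160 ± 149 to 676 ± 87.4 CPM (SD, n = 3; adjusted p = 4e-04). RCA2 had a higher mean, 12200 ± 1200 against 9830 ± 310 CPM (SD, n = 3). Its log2 fold change of 0.32 ± 0.20 (SE, adjusted p = 0.29) did not pass. GSTU1, a glutathione transferase of the detoxifying tau class, was higher, at 760 ± 85.7 against 376 ± 92.6 CPM (SD, n = 3), a log2 fold change of 1.02 ± 0.31 (SE, adjusted p = 0.022). In the diploid GSTU1 changed by 0.20 ± 0.31 (SE, adjusted p = 0.72), and the interaction test found no difference between the ploidies for any named gene. Of the 18 named genes, 1 was higher, 6 were lower and 11 did not pass. Over all genes, 6479 passed, 3279 higher and 3200 lower, and 1328 and 1195 of them differed at least 2-fold. LOC107429253 rose from 2.42 ± 0.544 to 221 ± 21.3 CPM (SD, n = 3; adjusted p = 2e-12) and LOC107412003 fell from 208 ± 12.2 to 3.19 ± 0.27 CPM (SD, n = 3; adjusted p = 2.9e-13), both as in the diploid. The GSTU1 call ended without autotetraploid control replicate 1 (0.86) or 2 (1.01) and without autotetraploid 6 h replicate 2 (0.94).

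At 12 h the autotetraploid showed the fall in rubisco activase seen in the diploid. RCA1 fell from 2710 ± 301 to 155 ± 24 CPM (SD, n = 3), a log2 fold change of −4.13 ± 0.23 (SE, adjusted p = 1.4e-10), and RCA2 from 9830 ± 310 to 2080 ± 436 CPM (SD, n = 3), a change of −2.24 ± 0.21 (SE, adjusted p = 1.6e-07). Catalase fell from 2260 ± 63.4 to 1290 ± 73.3 CPM (SD, n = 3; adjusted p = 9.4e-05) and GAPDH to 1080 ± 24.1 CPM (SD, n = 3; adjusted p = 4.4e-09). EXPA5 fell to 97 ± 53 CPM and EXPA4 to 166 ± 83.9 CPM (SD, n = 3), with adjusted p-values of 0.00038 and 0.0012. Of the 18 named genes, 9 were lower, none was higher and 9 did not pass. Over all genes, 7647 passed, 3611 higher and 4036 lower, and 1221 and 1987 of them differed at least 2-fold. Among the largest falls was LOC107423826, from 2840 ± 162 to 20.7 ± 6.08 CPM (SD, n = 3; adjusted p = 5.8e-14), and LOC107417223 rose from 0.555 ± 0.0989 to 56.8 ± 11.5 CPM (SD, n = 3; adjusted p = 2.1e-10). Scaling by library totals alone gave 5659 higher and 2988 lower genes, 65.4% higher beside 47.2%, with the median gene moved by 0.15 on the log2 scale. With only the 6 libraries compared in the model, 4759 genes passed, and EXPA4 did not.

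At 48 h the autotetraploid again had rubisco activase, GAPDH and catalase at or above the control level. Catalase was higher, at 3780 ± 288 against 2260 ± 63.4 CPM (SD, n = 3), a log2 fold change of 0.74 ± 0.13 (SE, adjusted p = 0.0015). TUA remained lower, at 569 ± 55.9 against 1160 ± 149 CPM (SD, n = 3), a change of −1.03 ± 0.14 (SE, adjusted p = 0.00045). RCA1 was higher at 4550 ± 450 CPM (SD, n = 3), a change of 0.75 ± 0.20 (SE, adjusted p = 0.021), although this call ended without autotetraploid control replicate 1 (0.72) or 2 (0.71) or without autotetraploid 48 h replicate 1 (0.71). Glu2 was lower, at 15.6 ± 5.05 against 58.3 ± 12.8 CPM (SD, n = 3), a change of −1.9 ± 0.4 (SE, adjusted p = 0.0052). The Glu2 call held without each compared library in turn. In the diploid at 48 h Glu2 changed by −0.57 ± 0.39 (SE, adjusted p = 0.47), and its interaction did not pass. In all, 2 named genes were higher, 3 lower and 13 did not pass. Over all genes, 3490 passed, 1570 higher and 1920 lower, and 371 and 1051 of them differed at least 2-fold. LOC107418400 rose from 0.686 ± 0.248 to 155 ± 93.4 CPM (SD, n = 3; adjusted p = 0.0021), and LOC107429331 fell from 30.2 ± 22.2 to 0.137 ± 0.0688 CPM (SD, n = 3; adjusted p = 0.00048). The latter belonged to a set of 172 genes that were at least 8-fold lower than in the autotetraploid controls. Its median level stood at log2 CPM values of −3.25, −3.95 and −4.25 in the 3 libraries at 48 h, at −2.02 in replicate 3 of the autotetraploid at 12 h, and between −0.84 and 1.67 in the other 20 libraries. In the diploid the set was lower at 48 h too, at 0.36, 0.23 and −0.84 beside 0.93, 0.74 and 1.67 in the diploid controls. This was not particular to 48 h there, since the diploid libraries stood at 0.32, −0.43 and −0.15 at 6 h. At 12 h they stood at 0.49, 0.07 and 0.03. The autotetraploid controls spread from −0.38 to 1.53. The count of calls was 1773 without autotetraploid control replicate 1, 1967 without autotetraploid 48 h replicate 1 and 881 with only the 6 libraries compared in the model. Scaling by library totals alone gave 1109 higher and 2178 lower genes, 33.7% higher beside 45%.

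**Figure D2:**
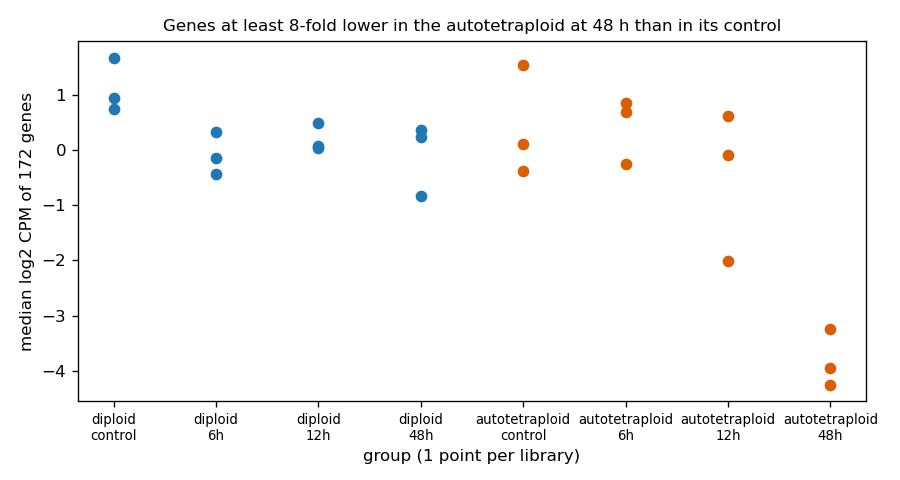
Median log2 CPM of the 172 genes at least 8-fold lower in the autotetraploid at 48 h than in its control (vertical axis), in each of the 24 libraries, 1 point per library, by group (horizontal axis). The 3 autotetraploid 48 h libraries lie between −4.25 and −3.25, and the next lowest point, at −2.02, is replicate 3 of the autotetraploid at 12 h.

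**Figure D3:**
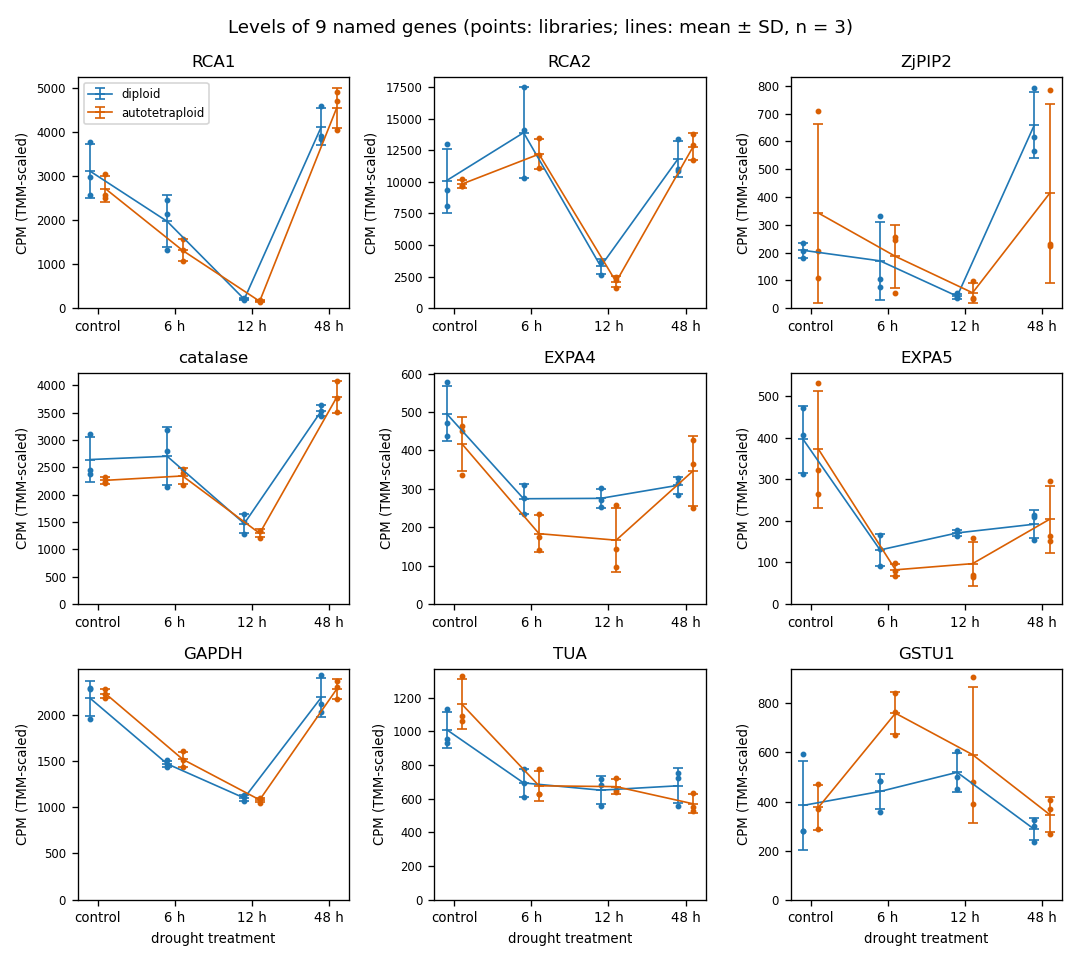
CPM of 9 named genes (vertical axes, each from 0) in controls and after 6, 12 and 48 h of drought (horizontal axes), in the diploid and the autotetraploid; points are libraries and lines join group means with SD bars (n = 3). RCA1 falls to 202 and 155 CPM at 12 h in the 2 ploidies and stands at 4120 and 4550 CPM at 48 h.

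The drought responses of both ploidies were then set side by side; the comparisons share no library. At 6 h, 4007 genes passed in the same direction in both, 2061 higher and 1946 lower, where independent lists of these sizes would share 374 and 318, and 1 gene passed in opposite directions. At 12 h, 5771 genes were shared, 2647 higher and 3124 lower, beside 528 and 627 for independent lists, and none passed in opposite directions. These were 74% of the genes called in the diploid and 75.5% of those called in the autotetraploid. At 48 h, 394 genes were shared, which is 75.8% of the 520 called in the diploid and 11.3% of the 3490 called in the autotetraploid, with 205 higher and 189 lower beside 17 and 17. RCA1, RCA2, catalase, GAPDH and TUA were among the 9 named genes lower in both ploidies at 12 h. Across the tested genes, which are not independent replicates, Pearson's r between the log2 fold changes of the ploidies was 0.368 at 6 h, 0.484 at 12 h and 0.259 at 48 h, and across genes called in at least 1 ploidy it was 0.736, 0.788 and 0.69. The value depended on how folds were estimated: over all genes it was 0.184, 0.301 and 0.185 by DESeq2, 0.687, 0.805 and 0.532 by limma, and 0.647, 0.747 and 0.484 with only the libraries compared in each model. The 48 h overlap was 29 and 140 without diploid control replicates 2 and 3, and 186, 112 and 69 without diploid 48 h replicates 1, 2 and 3. By DESeq2 it was 1190, and with only the libraries compared in each model it was 8.

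**Figure D4:**
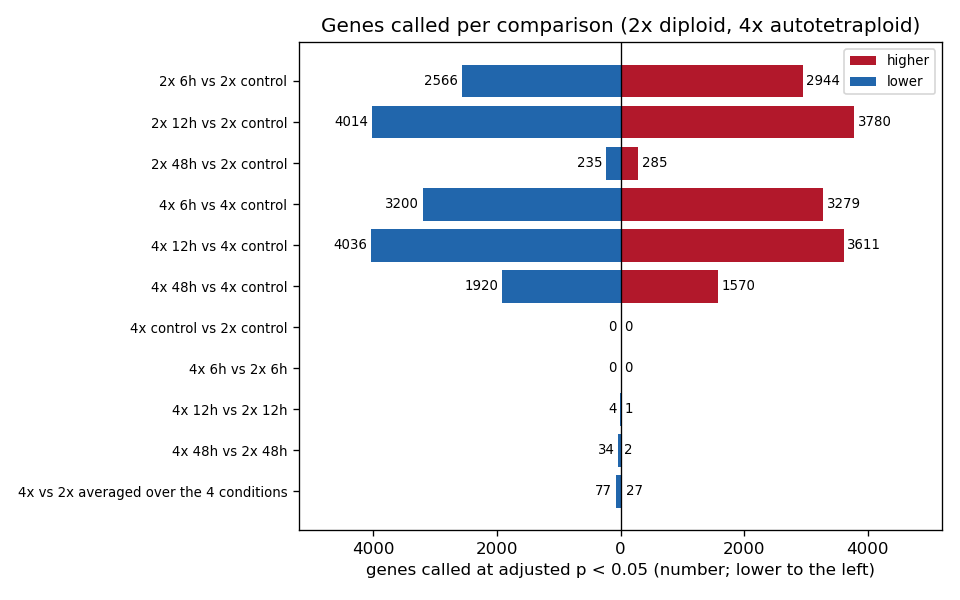
Number of genes called at an adjusted p under 0.05 in each comparison, higher to the right of 0 and lower to the left, with the counts printed beside the bars; 2x is the diploid and 4x the autotetraploid. The counts for drought at 6 and 12 h run from 2566 to 4036 in each direction, and those between the ploidies do not exceed 77.

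The direct comparisons of the ploidies asked which genes differed between autotetraploid and diploid leaves under the same treatment. In the controls no gene passed edgeR's quasi-likelihood test, with a smallest adjusted p of 0.12. A total of 2230 genes (8.63%) had an unadjusted p under 0.05, where a share of about 0.05 would with no difference. DESeq2 called 175 and limma 5. RCA1 stood at 2710 ± 301 CPM in the autotetraploid controls and 3110 ± 618 CPM in the diploid ones (SD, n = 3), GAPDH at 2230 ± 49.2 and 2180 ± 187 CPM (SD, n = 3), and none of the 18 named genes passed in any of the 4 treatments. Adjusted over the list alone, Glu2 and GMP passed at 48 h, each with an adjusted p of 0.038, and none in the other 3 treatments. At this depth and group size the test recovered 36% of 2-fold and 85% of 4-fold differences between simulated controls with 200 genes changed. One library mattered, since 63 genes passed without autotetraploid control replicate 3, and between 0 and 4 without any other. After 6 h again no gene passed, with 1919 (7.43%) at an unadjusted p under 0.05, 115 by DESeq2, none by limma and between 0 and 3 without any 1 library.

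After 12 h, 5 genes differed between the ploidies, 1 higher and 4 lower in the autotetraploid. At an unadjusted p under 0.05 there were 1372 genes, or 5.31%, near the share that no difference would give. LOC107422767 was lower, at 0.757 ± 0.449 CPM against 5.54 ± 1.33 CPM (SD, n = 3), a log2 fold change of −2.86 ± 0.39 (SE, adjusted p = 0.023), and LOC107420755 at 20.3 ± 1.92 against 33.6 ± 3.07 CPM (SD, n = 3; adjusted p = 0.047). LOC107433003, named because the count was so small and after its values were seen, was higher at 1.09 ± 0.153 against 0.218 ± 0.103 CPM (SD, n = 3; adjusted p = 0.047), a call that ended in 4 of 6 fits that left out a library. The LOC107420755 call ended in 5 of these 6, all but that without diploid 12 h replicate 1, with log2 fold changes of −0.81 to −0.68 against −0.73, and under all 3 other scalings. It also ended without a filter, with the replicate number as a block, by limma and with only the 6 libraries compared. The count was 10, 11 and 1 without diploid 12 h replicates 1, 2 and 3, and 3, 25 and 1 without autotetraploid 12 h replicates 1, 2 and 3. It was 131 by DESeq2 and 2 by limma, with the replicate number as a block, or with only the 6 libraries compared in the model. It was 0 without the genes in or varying with a set of 172 genes low in the autotetraploid at 48 h. LOC107422767, of the set, and 1 other called gene were removed by this. The remaining 3 kept their fold changes and unadjusted p-values. Their adjusted p-values rose to between 0.063 and 0.069, since the removed calls no longer counted in the ranking. The LOC107422767 call ended without autotetraploid 12 h replicate 1 (−2.64) or 3 (−2.62), and with only the 6 libraries compared.

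After 48 h, 36 genes differed, 2 higher and 34 lower in the autotetraploid, with 2153 (8.34%) at an unadjusted p under 0.05. LOC107429331 stood at 0.137 ± 0.0688 CPM in the autotetraploid and 21.3 ± 18.6 CPM in the diploid (SD, n = 3; adjusted p = 0.015), and was also among the genes that fell within the autotetraploid. LOC107411984 was higher in the autotetraploid, at 13.4 ± 0.235 against 8.97 ± 0.495 CPM (SD, n = 3; adjusted p = 0.031). LOC107432866 was higher at 109 ± 7.81 against 80.2 ± 3.2 CPM (SD, n = 3; adjusted p = 0.033), while at 6 h both ploidies held it at 609 ± 28.5 and 588 ± 14.1 CPM. Of the lower genes, 18 lay outside the set of 172 genes described above, and 4 of these varied with it within groups. Leaving out the set and the genes that varied with it gave a count of 8; this took out 20 of the 36, in part because the set was chosen as low in these libraries, and the adjusted p-values of 8 others rose to between 0.054 and 0.074. With the replicate number as a block the count was 10, and with only the 6 libraries compared in the model 8. The calls of LOC107411984 and LOC107432866 ended in both of these fits and by limma. That of LOC107429331 ended with only the 6 libraries compared and by limma. The count was 5 without diploid 48 h replicate 1, and 10, 10 and 11 without autotetraploid 48 h replicates 1, 2 and 3, and each of these named calls ended in some of those fits. DESeq2 called 434 genes and limma 6.

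Averaged over the 4 treatments, which gives 12 libraries against 12, 104 genes differed with ploidy, 27 higher and 77 lower in the autotetraploid, and 45 of them at least 2-fold. This contrast was added after the single-treatment results were seen. LOC107410511 was lower in the autotetraploid, at 3.23 ± 1.59 against 9.15 ± 3.35 CPM (SD, n = 12), a log2 fold change of −1.56 ± 0.24 (SE, adjusted p = 0.011), and the call held without each of the 24 libraries in turn. Within each treatment its means ran from 1.67 to 4.76 CPM in the autotetraploid and from 6.72 to 11 CPM in the diploid. LOC107415078 was higher, at 7.46 ± 2.22 against 4.7 ± 1.26 CPM (SD, n = 12; adjusted p = 0.035), a call lost in 11 of the 24 fits that left out a library, with log2 fold changes from 0.59 to 0.72. None of the 18 named genes passed, RCA1 having a change of −0.26 ± 0.10 (SE, adjusted p = 0.26) and GAPDH one of 0.03 ± 0.04 (SE, adjusted p = 0.82). Over 12 chromosomes, as named in the ASM3175591v1 assembly, the median log2 difference per chromosome lay between −0.02 and 0.0062, relative to a scaling that sets the typical gene to no difference. Leaving out any 1 library gave between 20 and 255 calls, the lowest without autotetraploid control replicate 2 and the highest without diploid control replicate 3, and moved the count by over 1.5 times for every library except autotetraploid 48 h replicate 1. DESeq2 called 882 genes, and the model with the replicate number as a block 45.

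Whether the drought response itself differed with ploidy was tested as an interaction at each time. No gene passed at 6, 12 or 48 h by edgeR's quasi-likelihood test, with smallest adjusted p-values of 0.23, 0.44 and 0.25. At an unadjusted p under 0.05 there were 1650, 1211 and 1626 genes, or 6.39%, 4.69% and 6.3% of those tested. With no difference, a share of about 0.05 would lie there. DESeq2 called 98, 80 and 162 and limma none. Among the 18 named genes the smallest adjusted p was 0.77 at 6 h, for the polyphenol oxidase gene PPO, 1 at 12 h and 0.75 at 48 h, for Glu2. PPO at 6 h had the widest contrast of the named genes, 1.47 on the log2 scale, from 61.1 ± 13.1 to 38.1 ± 7.01 CPM in the diploid and from 44.6 ± 11 to 77 ± 31.3 CPM in the autotetraploid (SD, n = 3), with neither change past the threshold. With edgeR on all libraries, the counts of 3490 autotetraploid and 520 diploid genes at 48 h came with no gene shown to respond differently. By DESeq2 there were the 162 given above. Leaving out single libraries gave edgeR at most 5, 7 and 5 genes at the 3 times.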

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

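The removal of genes that switch within a group or covary with the set lowest in the autotetraploid at 48 h, and all settings for the average over treatments and the response size, were chosen after the data were seen; the other settings were planned. With only the compared libraries in each model, and so fewer residual degrees of freedom, calls were 3570 for diploid drought at 6 h and 25 at 48 h, 4759 and 881 for the autotetraploid at 12 and 48 h, 9, 5, 2 and 8 for the ploidies in control, 6, 12 and 48 h, and 3 and 1 for the interactions at 6 and 48 h; shared calls were 2612, 3484 and 8, and r was 0.647, 0.747 and 0.484. Requiring a 2-fold change, a stricter rule, left 1820, 3014 and 181 diploid and 2523, 3208 and 1422 autotetraploid drought calls, 1297, 2191 and 133 shared, 3 between the ploidies at 12 h and 45 on average. An adjusted p under 0.01 left 3293, 5164 and 10, then 4073, 5019 and 1314, with 2506, 3799 and 10 shared, 0 and 2 between the ploidies at 12 and 48 h, and 9 on average. DESeq2 called 1827 genes for the diploid at 48 h, and 175, 115, 131 and 434 between the ploidies. It called 882 on average and 98, 80 and 162 for the interactions, with 1190 shared at 48 h and r of 0.184, 0.301 and 0.185. In the simulated control ploidy comparison DESeq2 made 73 false calls among 211, and edgeR 3 among 124. Whether such false calls make up the excess here was not tested. limma on FPKM called 5, 2 and 6 between the ploidies in control, at 12 h and at 48 h, with r of 0.687, 0.805 and 0.532; the cause was not tested. The 5 ploidy calls at 12 h became 3 with relative log expression, upper quartile or library size only scaling, and 2 without a filter. They became 0 without the covarying genes, which also left 8 at 48 h. Of these losses, 3 at 12 h and 8 at 48 h were genes that were not themselves removed. Their adjusted p-values rose because called genes left the ranking on which the adjustment rests. Their fold changes and unadjusted p-values stayed as before. For r, no filter gave 0.284, 0.375 and 0.183, a mean of at least 1 CPM 0.465, 0.62 and 0.309, leaving out switching genes 0.475, 0.573 and 0.34, and only called genes 0.736, 0.788 and 0.69.

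Leaving out 1 library gave 4253 to 4971, 6357 to 7139 and 36 to 849 diploid calls, 4644 to 6086, 6046 to 6923 and 1773 to 3152 autotetraploid calls, 0 to 63, 0 to 3, 1 to 25 and 5 to 43 between the ploidies, 20 to 255 on average, and 0 to 5, 0 to 7 and 0 to 5 for the interactions. Shared calls ran from 3285 to 3931, 4962 to 5677 and 29 to 529, and r from 0.3 to 0.34, 0.408 to 0.451 and 0.189 to 0.238. A group left with 2 libraries was assumed to vary like the others. The difference in response size ran from 0.0322 to 0.155 at 6 h, −0.0328 to 0.0787 at 12 h and −0.00857 to 0.295 at 48 h. It was negative in 5 of 12 fits at 12 h, without diploid control replicate 2 or 3 or any diploid 12 h library, and at 48 h without diploid control replicate 2 or diploid 48 h replicate 2 (−0.00101). Libraries of the same number did not deviate together (median r −0.00273, from −0.0975 to 0.103, and 6 of 24 libraries highest with their own number), so the numbers were not taken to pair them. With the replicate block the ploidy calls were 2 at 12 h, 10 at 48 h and 45 on average, and no other count moved by over 1.5 times. Of 74 calls of named or picked genes, DESeq2 kept all 74, limma 62, the block 66 and the fits on compared libraries 48 of 70, and none reversed; 25 of 40 calls of named genes held without each compared library in turn. The gene list tests and their alternatives were not run, since no description was paired with the identifiers. What depth limits was checked by thinning all libraries to 30750412 counts, which gave 3631 autotetraploid calls at 48 h beside 3490.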

Other observations

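All tests in this part were chosen after the results were seen. The drought response was traced over time with genes chosen in one ploidy and read in the other, which shares no library with the choice. The 3780 genes higher at 12 h in the diploid had median log2 changes in the autotetraploid of 0.45 at 6 h, 0.57 at 12 h and 0.11 at 48 h, and the 4014 lower genes −0.54, −0.84 and −0.05. The 4036 genes lower at 12 h in the autotetraploid read −0.49, −0.83 and −0.08 in the diploid. Of the genes chosen at 48 h, the 285 higher in the diploid read 0.27, 0.25 and 0.56 in the autotetraploid, and the 235 lower ones −0.31, −0.31 and −0.90, with 98.3% of the latter lower there at 48 h. The 1570 genes higher at 48 h in the autotetraploid read 0.14, 0.13 and 0.31 in the diploid, and the 1920 lower ones −0.38, −0.48 and −0.51. LOC107413003 was lowest at 12 h in both ploidies: in the order control, 6, 12 and 48 h it stood at 24.2 ± 3.13, 3.64 ± 0.395, 0.11 ± 0.117 and 23.1 ± 2.44 CPM in the diploid and at 19 ± 1.88, 2.79 ± 0.582, 0.227 ± 0.205 and 19 ± 1.85 CPM in the autotetraploid (SD, n = 3). LOC107432866 had another course, highest at 6 h in both, at 588 ± 14.1 and 609 ± 28.5 CPM, and at 392 ± 25.7 and 369 ± 16.6 CPM at 12 h (SD, n = 3).

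Protein-coding genes passed the drought tests more often than gene models without a name, at 35.4% against 18.3% in the diploid at 12 h and 16.5% against 5.94% in the autotetraploid at 48 h; their median levels were 18.7 and 1.47 CPM. Over the genes shared by both ploidies, the mean signed response per library was 0.987 ± 0.02 on the log2 scale in the diploid and 1.07 ± 0.034 in the autotetraploid at 6 h (SD, n = 3; exact two-sided p = 0.1, adjusted p = 0.15). It was 1.13 ± 0.026 and 1.16 ± 0.052 at 12 h (exact p = 0.6, adjusted p = 0.6) and 0.978 ± 0.066 and 1.12 ± 0.04 at 48 h (exact p = 0.1, adjusted p = 0.15). The smallest p that 3 against 3 libraries allow is 0.1, and no difference in response size was established. All scores of a ploidy were taken from the same control mean, and the error of that mean enters neither the SD nor the exact p. The genes were also chosen in these same libraries. Leaving out single libraries moved the 6 h difference between 0.0322, without diploid control replicate 3, and 0.155, without autotetraploid control replicate 3. Such omissions made the 12 and 48 h differences negative in 5 and 2 of 12 fits.

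Some genes stood near 0 in one library and high in another of the same group. This held for 995 genes, 3.85% of those tested, in at least 1 group; LOC107431910 lay between 45.7 and 63.1 CPM in 11 libraries and at 0.0312 CPM or less in the other 13, with both states in each of the 8 groups. The tables argue against counting noise at low depth: counts redrawn with that noise alone around the group means gave 0 such genes in each of 10 draws, against 2354 to 2490 at 1/50 of the depth. Reads counted for the adjacent gene remain open: it gained a similar level in 22.4% of cases, beside 18.2% for a gene 10 places away, but only 331 of the 995 genes could be checked, and LOC107431888, next to LOC107431910, stood at 66.3 to 109 CPM in those 13 libraries and at 29.7 to 58.4 CPM in the 11. Reads shared with a near-identical copy remain open too: 55.9% of these genes are LOC symbols outside the reference table, against 22.2% of all tested genes, but without sequences this cannot be told apart from models that later annotations dropped, and no biological explanation was tested.

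The 172 genes at least 8-fold lower in the autotetraploid at 48 h also varied together elsewhere. In the 18 libraries of the 6 other groups, their deviations from the group means had a median pairwise r of 0.4, against −0.00664 to 0.0386 for 1000 random lists of as many genes, and 32% of the other genes lower at 48 h varied with them, against 4.01% of those higher, 26.5% of those lower in the diploid at 48 h and 10.3% of all tested. The tables argue against a difference in depth, since 160 of the 172 remained lower with all libraries thinned to the lowest total, while gene length was not settled: the trend of the fold with length was nearly flat, from −0.0509 to 0.018 between its 1st and 99th percentile, so that removing it hardly moved any gene, with a median of −4.9 before and −4.92 after for the 140 genes of the set with a length. A second tissue or cell state, present in a varying share of the harvested leaves, needs such joint variation within groups. Genes regulated together would vary jointly too, so the r cannot tell these apart. The random lists were matched for mean level and not for variability, which also limits the comparison. A second tissue or cell state thus stays open, and which one was not tested. A response of the autotetraploid to 48 h of drought stays open as well and was not tested, since the genes were chosen for being low in those libraries.

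Few genes were called at 48 h beside 6 and 12 h in the diploid. A larger spread between libraries would lower the count, but the median SD within the group was 1.01 times that at 12 h. The hour of day at harvest could contribute, since 6 and 12 h fall at other hours than 48 h relative to the start and the plants grew under a light and dark cycle. The slope of the diploid folds on the 12 h folds of the autotetraploid was 0.88 at 12 h and 0.099 at 48 h, which a return to the starting hour and an acclimation to drought both predict. Controls at matched hours were not analysed here, so these cannot be told apart.

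Other splits of the same libraries were tested for each count of genes. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Only 1 of the 10 gave as many genes, the real one, in each drought comparison and in the ploidy comparisons at 12 and 48 h, while for the ploidies in control and at 6 h all 10 did, as any split must where the real count is 0. The highest count of another split was 1, 3 and 14 beside the real 7794 and 520 in the diploid at 12 and 48 h and 7647 in the autotetraploid at 12 h, and 1 beside 5510, 6479 and 3490 in the remaining drought comparisons. Between the ploidies it was 3 and 1 beside 0 and 0, and 3 and 2 beside 5 and 36. For the average over treatments, 1 of 50 splits gave as many as 104 genes, the real one, with 3 in the highest other. The other splits drawn thus did not reproduce this count, but the contrast was chosen after the results were seen. The libraries may not be separate plants, so chance differences between plants are not excluded. For the interactions all 50 of 50 splits gave as many as the 0 observed, which holds for any split, so these say nothing about chance. The highest others there were 1, 3 and 31 genes; the split with 31 at 48 h may point to a structure among the libraries, which was not tested.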
